A study of Arabidopsis thaliana with 4 samples.

How the data were processed

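Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on Arabidopsis thaliana seedlings with an anti-Myc antibody. Per the labels' protocols, seeds were stratified for 3 days at 4 °C, exposed to white light for 3 to 4 h to induce germination and then kept in darkness for 4 days. The 4 libraries were 1 anti-Myc ChIP library of wild type (Col), 1 anti-Myc ChIP library of TCP4 overexpression seedlings (labelled mTCP4) and 1 input library of each genotype. With 1 library per group there is no replicate error, and no test between the genotypes was made.

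A single peak list of mTCP4 against Col was used. Per the submitters' processing notes, the tools were Bowtie 0.12.9 and MACS2 2.1.1 and the genome build was TAIR10. Whether the input libraries entered the peak calls, and the calling threshold, are not given in the sources used here. Per the file headers, each line holds the interval, the summit position and the name of a peak. The deposited pileup is a signal, the scaled number of fragments covering the summit. The deposited fold is the ratio of the pileup at the summit to the control level there, on a linear scale. The deposited p-values and q-values are given as −log10. The deposited positions are used as listed. The interval of 7469 of the 7470 summits runs 5000 bp to each side of the summit, and the remaining interval, at the start of chromosome 1, is 6648 bp long. The intervals therefore do not measure peak width, and the summit was taken as the position of each peak.

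The control level at each summit was recovered from the deposited pileup and fold, with the pseudocount of 1 that MACS2 adds to both. All pileups were whole multiples of 0.737 within 0.01 (100% of summits), so 1 step was taken as 1 fragment. The deposited p-values were recomputed from the pileup and the recovered control level with a Poisson distribution for 100% of summits, within 0.05 on the log10 scale. The lowest control level, 12.9, occurred at 1368 summits (18.3%). The number of fragments at a summit had a median of 86 and ran from 43 to 355. Library totals were not analysed here. Intervals of fold values are exact 95% Poisson intervals of the number of fragments with the control level held fixed. They cover counting error only and leave out differences between seedling batches. For the median summit the bounds lay 19.7% below and 23.1% above the fold.

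Gene names, positions and classes came from a RefSeq gene table of assembly TAIR10.1, with 37899 nuclear genes, of which 27444 are protein-coding. No gene coordinate of that assembly is printed. Summit coordinates are those of the deposited list, and distances to gene ends combine the list with the gene table. The shared coordinate system was checked by moving the summits by up to 1000 bp in steps of 100 bp, separately in 20 segments of the chromosomes. In 20 of 20 segments the share of summits inside gene bodies was lowest within 200 bp of no shift.

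The gene table gives no strand. The windows fixed before the data were examined, 1000 bp upstream to 200 bp downstream of the transcription start, were therefore replaced by windows at both gene ends, from 1000 bp outside to 200 bp inside each end. A gene with a summit in either window is called bound, as a short name for holding a summit. No genome sequence was used here, so the planned tests of TCP motifs, the G-box and the PIF element were not run.

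Shares of summits by position were compared with 1000 circular shifts of all summits along each chromosome, by at least 20000 bp, with a two-sided permutation p whose smallest possible value is 0.001. The 25 gene lists were fixed before the data were examined. For each list, bound members were compared with bound genes among all other protein-coding nuclear genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 25 lists and a threshold of 0.05. Shares have exact (Clopper-Pearson) 95% intervals. Genes and summits are the units of these tests and are not replicates. Of the names in the lists, 5 had no match in the gene table. They were RVE6, PAP2, TCP6, BBX11 and PIF8. The ribosomal protein list was taken by symbol and includes a plastid protein, RPS9. Some genes belong to more than 1 list.

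The genes named in the text follow a rule fixed before the data were examined, with gene ends later put in place of transcription starts. It takes TCP4, PIF3, SAUR16, SAUR50, MIR319A, MIR319B and MIR319C whatever their values, the protein-coding gene with the end nearest to each of the 12 summits with the highest fold, and up to 4 bound members of each list with the highest fold. Alternatives chosen before the data were examined were a stricter q of 1e-05, the upper 50% of summits by fold, and windows of 500 and 2000 bp. Others chosen then were gene bodies included, whole intervals, all annotated genes and circular shifts for the gene lists. Alternatives added after the data were seen were 1 summit per numbered peak, each summit given to its nearest gene within 1000 bp, only summits with the lowest control level, and 10000 gene sets matched on the decile of the summed gaps to both neighbouring genes.

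The list test was tested on the 27444 genes with simulated summits at random positions, as many per chromosome as in the real list. Unlike the real summits, these were not gathered at gene ends, and the simulated lists drew genes singly. The rates below thus do not cover clustered summits or tandem gene families. The list test recovered 100% of 100 planted lists of 30 genes in which 15 members were given a summit. Of 200 random lists, 4.5% had an unadjusted p under 0.05. The gap-matched sets recovered 100% of the same planted lists, with 2.5% of 200 random lists under 0.05, and circular shifts recovered 100% of the 20 planted lists tried. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9.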

Results

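To find potential targets of TCP4, a CIN-type TCP transcription factor of Arabidopsis, anti-Myc ChIP-seq was carried out on 4-day-old dark-grown seedlings of a TCP4 overexpression line and of wild type. Each genotype had 1 ChIP library and 1 input library, so the values below have no replicate error. The deposited list of mTCP4 against Col held 7470 summits in 6220 numbered peaks, 1090 of them with more than 1 summit. Fold enrichment and q are the authors' own values for each summit, and coordinates are those of build TAIR10. A gene is called bound here when a summit lies within 1000 bp outside or 200 bp inside either of its ends. Fold values in the text are followed, for the genes the series is about, by 95% intervals of counting error. For the median summit this interval reached from 19.7% below to 23.1% above the fold.

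The series title names TCP4, the SAUR family genes SAUR16 and SAUR50, and PIF3, a phytochrome-interacting factor that acts in darkness. All 4 genes were bound. SAUR50 (AT4G34760) had a summit at position 16583014 of chromosome 4, inside the gene and 61 bp from its higher-coordinate end, with a fold of 6.31 (5.44 to 7.27). SAUR16 (AT4G38860) had a summit at position 18129716 of chromosome 4, outside the gene and 521 bp from its lower-coordinate end, with a fold of 4.33 (3.60 to 5.16). A higher fold, 12.5 (11.0 to 14.1), was listed in the same cluster at position 18125796, in the gap between SAUR14 at 237 bp and SAUR15 at 261 bp. That summit lay 4441 bp from SAUR16. The intervals of these 2 summits did not overlap.

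PIF3 (AT1G09530) had a row of summits on chromosome 1. One lay 605 bp outside its lower-coordinate end at position 3075163, with a fold of 3.65 (2.85 to 4.61), and another 83 bp outside it at position 3075685, with a fold of 4.63 (3.90 to 5.47). A further summit lay inside the gene at position 3076704, 936 bp from the nearest end, with a fold of 4.40 (3.65 to 5.26). The interval of each of these overlapped those of the others. A summit with a fold of 4.88 lay farther out, 3148 bp from the gene. TCP4 itself (AT3G15030) had a summit 795 bp beyond its higher-coordinate end, at position 5064947 of chromosome 3, with a fold of 4.82 (3.99 to 5.77). This position lies inside the neighbouring gene AT3G15040, and no summit was listed inside TCP4. The 3 genes of miR319, the microRNA that targets TCP4 transcripts, had no summit in their windows. The nearest summits lay 4640 bp from MIR319A with a fold of 3.20, 4495 bp from MIR319B with a fold of 5.33 and 1575 bp from MIR319C with a fold of 2.05.

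**Figure D1:**
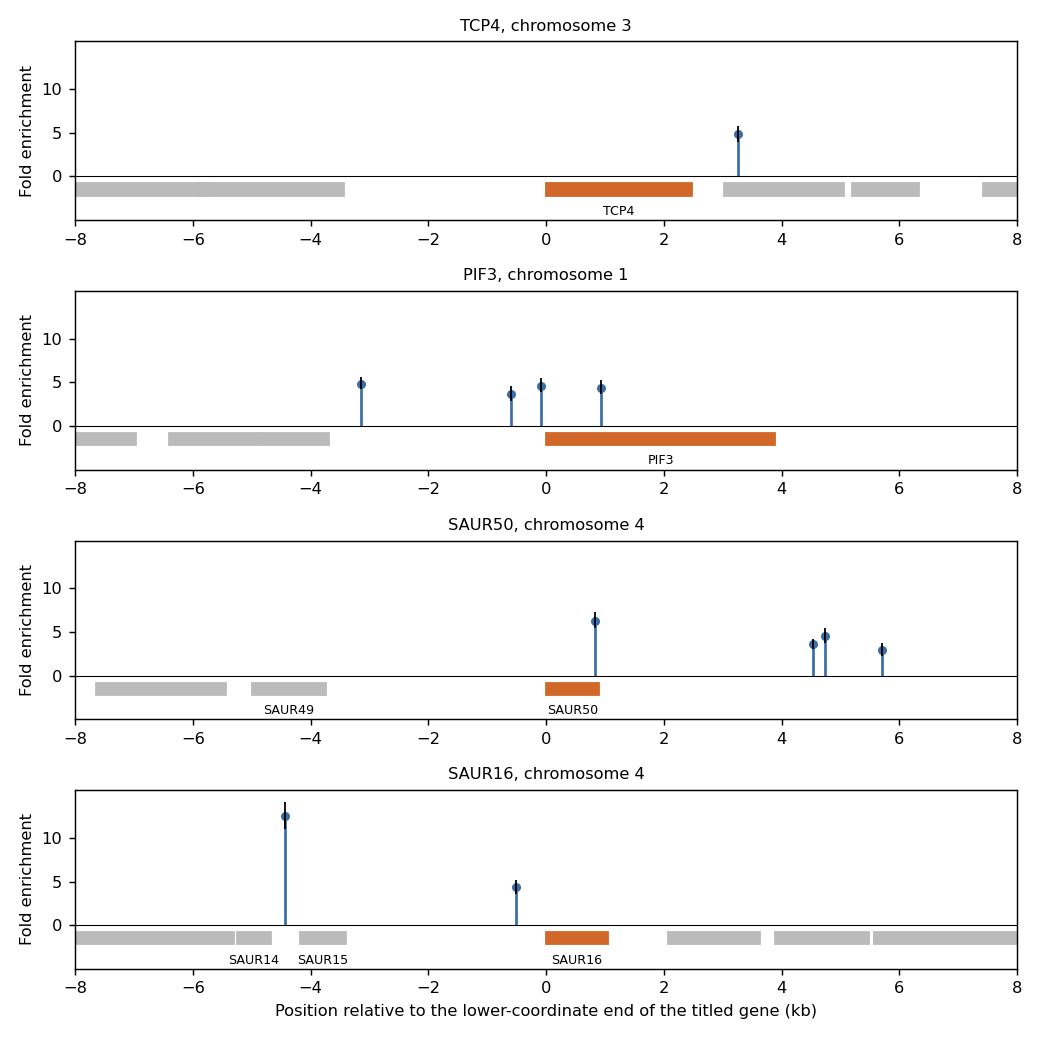
Summits around TCP4, PIF3, SAUR50 and SAUR16. The x axis is the position in kb from the lower-coordinate end of the titled gene, the blue lines reach up to the fold enrichment of each summit with its 95% counting interval in black, and bars under the axis are protein-coding genes, the titled gene in orange and its neighbours in grey. The highest fold is 12.5, at the summit between SAUR14 and SAUR15, against 4.33 at the summit nearest to SAUR16.

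The 12 summits with the highest fold lay inside or between genes of several kinds. The highest fold, 16.4, was 356 bp outside AT1G52790 on chromosome 1, at position 19663657. The next was inside AN3 (AT5G28640), a coactivator of leaf cell proliferation, at position 10648832 of chromosome 5 with a fold of 15.4. Summits with folds of 15.4 and 14.3 lay 867 bp outside KLCR2, a kinesin light chain-related gene, and 176 bp outside the homeobox gene KNAT4. SHY2, the Aux/IAA repressor also named IAA3, was the gene nearest to a summit with a fold of 13.5 at 2120 bp. ZFP8, a zinc finger gene, had a summit with a fold of 12.6 at 814 bp. The summit between SAUR14 and SAUR15 was also among the 12 highest. The other summits among them were 1213 bp from WRKY61 (13.3), 2254 bp from AT1G61900 (12.7), 3553 bp from AT5G41401 (13.1), and 2692 and 4654 bp from BRG1 (14.2 and 12.4). Over all summits, fold ran from 1.67 to 16.4 with a median of 3.43 and quartiles of 2.76 and 4.72, and 78 summits had a fold above 10. The median −log10 q was 14.2 and the lowest 3.46.

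Summits gathered at the ends of protein-coding genes. Of the 7470 summits, 4650 (62.2%) lay within 1000 bp outside or 200 bp inside a gene end, against a mean of 42.2% in 1000 circular shifts (95% of shifts 39.1 to 45.6%; two-sided permutation p = 0.001, the smallest they can give). Gene bodies held fewer summits than the shifts gave, 2211 (29.6%) against 54.1% (permutation p = 0.001). Summits more than 1000 bp from any protein-coding gene made up 25.4%, against 25.4% in the shifts (permutation p = 0.986). The excess did not stop at 1000 bp, however. The bin from 1000 to 1100 bp outside held 166 summits against a mean of 77.4 in 100 shifts. Each 100 bp bin up to 3000 bp was above that mean, the last with 32 against 20.6. The equal shares thus join an excess near the windows with a shortfall farther out. Outside genes, the median distance to the nearest end was 671 bp. The fullest 100 bp bin lay just outside the gene ends, with 660 summits against a mean of 265 in 100 shifts. Without strand, upstream and downstream ends were not told apart.

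**Figure D2:**
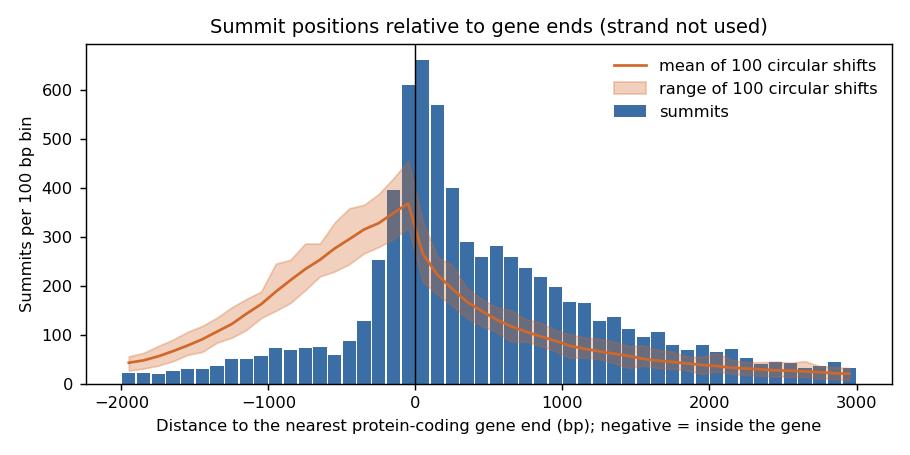
Number of summits per 100 bp bin by distance in bp to the nearest protein-coding gene end, with distances inside genes negative. Bars are the deposited summits, the orange line and band are the mean and the range of 100 circular shifts. The bin from 0 to 100 bp outside the ends is the fullest, with 660 summits against a mean of 265.

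In all, 4778 of 27444 protein-coding genes (17.4%) were bound, against a mean of 3204 in the shifts (95% of shifts 2959 to 3484). Of these, 3628 had 1 summit in their windows, 1150 had 2 or more and 244 had 3 or more. A summit in a window can lie inside a neighbouring gene, as at TCP4. Among the genes named below, this was so for the summits given for HEMB1, PSAP, GRF1, CKX6 and HTB4. Chromosomes held 1973, 1150, 1430, 1145 and 1772 summits from chromosome 1 to 5, or 26.2 to 28.0 per 100 protein-coding genes. The count of bound genes fell to 2532 with the upper 50% of summits by fold and to 719 with only the summits at the lowest control level, and it was 13282 when whole intervals were used in place of summits.

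Of the 25 gene lists, 12 held summits more often than other genes after adjustment and none less often (Fisher's exact test, two-sided, Benjamini-Hochberg over 25 lists). With only the 1368 summits at the lowest control level, 2 of these 12 lists still passed, ethylene genes and genes reported elsewhere as targets. The ratio of bound shares was 0 for Aux/IAA and clock genes and 1.96 to 5.47 for the others that lost their call, with 719 genes bound in all. With all summits, 3 of the lists that passed were of auxin genes. In the SAUR family, small auxin-induced RNAs that act in cell expansion, 24 of 79 genes (30.4%) were bound, through 23 distinct summits, against 17.4% of other genes (adjusted exact p = 0.0114). The highest folds were at SAUR14 and SAUR15 (12.5 at their shared summit), SAUR78 (7.72) and SAUR48 (7.11). Among Aux/IAA repressors 14 of 29 were bound (adjusted exact p = 0.000537), with IAA8 (8.87), IAA18 (6.10), IAA4 (5.73) and IAA11 (5.71) highest. Genes of auxin synthesis, transport and response were bound in 15 of 29 cases (adjusted exact p = 0.000164). They included YUC6 (6.65) and YUC2 (4.64) of auxin synthesis, the transporter PIN4 (4.65) and the receptor TIR1 (4.54). With only the summits at the lowest control level 0 of 29 Aux/IAA genes were bound, and the adjusted p of this list ran from 0.000415 to 1 over the alternatives. The SAUR call ended when each summit was given to its nearest gene only (17 of 79, adjusted exact p = 0.171), with the lowest control level (adjusted exact p = 0.176) and under circular shifts (adjusted permutation p = 0.0777). Its adjusted p ran from 0.000804 to 0.176 over the alternatives. The call of auxin synthesis, transport and response ended with the upper 50% of summits (6 of 29, ratio 2.25 against 2.98 with all summits, adjusted exact p = 0.082), and its adjusted p ran from 1.36e-08 to 0.391.

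The other plant hormones showed bound shares from 35.7 to 69.6%. Jasmonate genes had 16 of 23 bound (69.6%, adjusted exact p = 1.23e-06), including the repressors JAZ1 (10.4) and JAZ3 (5.84) and the synthesis genes LOX2 (9.39) and AOC1 (5.45). Ethylene genes had 13 of 21 bound (61.9%, adjusted exact p = 5.82e-05), with the synthesis genes ACO4 (6.46), ACS8 (5.59) and ACS5 (4.89) and the receptor EIN4 (4.41). Brassinosteroid genes had 8 of 15 bound (53.3%, adjusted exact p = 0.00526), with the receptor BRI1 (6.89), the transcription factors BZR1 (4.58) and BES1 (3.20) and the synthesis gene DWF4 (3.18). Cytokinin genes had 10 of 28 bound (35.7%, adjusted exact p = 0.0428), with the response regulators ARR16 (7.71) and ARR8 (7.63) and the oxidases CKX7 (6.05) and CKX6 (5.69). Gibberellin genes, with 7 of 19 bound (36.8%), did not pass (adjusted exact p = 0.067). They passed with windows of 500 or 2000 bp, gene bodies included, the upper 50% of summits or nearest genes only, at ratios of 2.56 to 3.48. GAI, a DELLA repressor, had a fold of 7.96, GA2OX1 7.34, and the receptors GID1B and GID1C 5.79 and 4.74. With the upper 50% of summits the jasmonate and brassinosteroid calls ended. Jasmonate genes had 5 of 23 bound (ratio 2.36 against 4.01 with all summits, adjusted exact p = 0.0917). Brassinosteroid genes had 2 of 15 bound (ratio 1.45 against 3.07, adjusted exact p = 0.744). The cytokinin call ended under circular shifts (adjusted permutation p = 0.146), where its ratio of bound shares, 2.05, was 2.0 times the mean ratio of the shifts. It also ended with gap-matched sets, with the number bound at 1.88 times their mean (adjusted permutation p = 0.118). Over the alternatives, adjusted p ran from 6.56e-10 to 0.107 for jasmonate, from 0.000309 to 0.744 for brassinosteroid, from 0.001 to 0.15 for cytokinin and from 0.000428 to 0.66 for gibberellin genes.

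Light and clock genes were also bound more often. Of the phytochrome and light signalling list 19 of 39 genes (48.7%) were bound (adjusted exact p = 5.82e-05). Among them were the phytochrome-interacting factors PIF4 (6.53), PIF5 (6.33) and PIF7 (5.54), besides PIF3, and the B-box gene BBX28 (7.38). Of the clock genes 8 of 17 (47.1%) were bound (adjusted exact p = 0.0114), with PRR9 (10.1), GI (5.77), CCA1 (4.82) and LUX (4.52) highest. This call ended under circular shifts (adjusted permutation p = 0.0849), where the observed ratio of bound shares, 2.71, was 2.67 times the mean ratio of the shifts. With only the summits at the lowest control level 0 of 17 clock genes were bound, and the adjusted p ran from 0.00861 to 1 over the alternatives. The lists of chlorophyll synthesis (3 of 16, adjusted exact p = 0.852) and of light-harvesting and photosystem proteins (7 of 45, adjusted exact p = 0.882) did not pass. In the first, PORB (6.73) and PORA (5.77), which reduce protochlorophyllide, and HEMB1 (2.30) were bound. In the second, PSAP (7.69), LHCA2 (6.58), LHCB2.1 (5.95) and PSAK (3.03) had the highest folds. With each summit given to its nearest gene only, 2 of 45 genes of the second list were bound (ratio 0.293, adjusted exact p = 0.0951).

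TCP genes other than the CIN type had 8 of 14 bound (57.1%, adjusted exact p = 0.00331), with TCP23 (7.43), TCP7 (5.45), TCP8 (5.10) and TCP14 (4.13) highest. Of the 8 CIN-type genes 3 were bound, TCP5 (5.63), TCP4 (4.82) and TCP17 (3.83), which did not pass (adjusted exact p = 0.233). With windows of 500 bp 0 of 8 CIN-type genes were bound, and with windows of 2000 bp 4 of 8. With nearest genes only 2 of 8 were bound, and the list passed in no alternative. Genes reported elsewhere as targets of TCP4 or its close relatives were bound in 8 of 11 cases (72.7%, exact 95% interval 39.0 to 94.0%, adjusted exact p = 0.000419). They included KRP1 (11.7), an inhibitor of cyclin-dependent kinases, LOX2 and ARR16 with the folds given above, and the flowering regulator CO (4.41). Expansins and xyloglucan endotransglucosylases, enzymes and proteins of wall loosening, had 18 of 57 bound (31.6%, adjusted exact p = 0.0183). Split by symbol after the data were seen, 13 of 33 XTH genes (39.4%) and 5 of 24 EXPA genes (20.8%) were bound. The expansins were thus near the 17.4% of all protein-coding genes. The highest folds of the list were all at XTH genes, XTH7 (9.39), XTH27 (7.38), XTH9 (7.11) and XTH18 (6.23). The call of the whole list ended under circular shifts (adjusted permutation p = 0.114), where its ratio of bound shares, 1.82, was 1.85 times the mean ratio of the shifts. It also ended with gap-matched sets, with the number bound at 1.69 times their mean (adjusted permutation p = 0.0614). The adjusted p of the list ran from 0.00129 to 0.391.

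The remaining lists did not pass. The core cell cycle list had 7 of 47 bound (14.9%, adjusted exact p = 0.882), with KRP1 and the cyclins CYCD3;2 (5.74), CYCD1;1 (4.76) and CYCD4;1 (4.73). Leaf and boundary patterning had 7 of 24 bound (adjusted exact p = 0.251), with the growth-regulating factors GRF5 (5.96), GRF1 (5.47) and GRF2 (4.48) and AN3 (4.11 in its window, below the summit farther inside the gene). Flowering time had 6 of 17 bound (adjusted exact p = 0.165), with AP1 (10.5), TEM1 (7.89), SOC1 (6.16) and SPL3 (5.39). Both of these lists passed in some alternatives, with adjusted p from 0.0136 to 0.691 for patterning and from 0.00591 to 0.691 for flowering. Secondary wall and lignin had 5 of 24 bound (adjusted exact p = 0.743), with VND2 (5.30), PAL2 (3.11), 4CL1 (3.06) and CAD5 (2.80). Flavonoid synthesis had 2 of 12 bound (adjusted exact p = 1), TT8 (7.19) and MYB11 (2.89).

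The 4 control lists, chosen for genes with no stated link to TCP4, gave no single background, with bound shares from 7.84 to 28.6%. The highest, of core histones, was close to that of the SAUR list (30.4%), which passed. Ribosomal proteins had 4 of 51 bound (7.84%, adjusted exact p = 0.165), RPL5A (5.46), RPL10C (4.09), RPL23AB (3.67) and the plastid protein RPS9 (2.47). Core histones had 6 of 21 bound (28.6%, adjusted exact p = 0.336), with HTR12 (6.98), HTA12 (4.37), HTA10 (4.26) and HTB4 (3.12) highest. Heat shock genes and chaperones had 6 of 45 bound (13.3%, adjusted exact p = 0.736), with HSFA1E (3.85), HSP81-3 (3.74), and HSP70-1 and HSP70-2 at 1 shared summit (2.63). Actins, tubulins and ubiquitins had 5 of 38 bound (13.2%, adjusted exact p = 0.796), with TUB4 (6.45), ACT7 (5.31), UBQ10 (2.56) and UBQ11 (2.55).

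**Figure D3:**
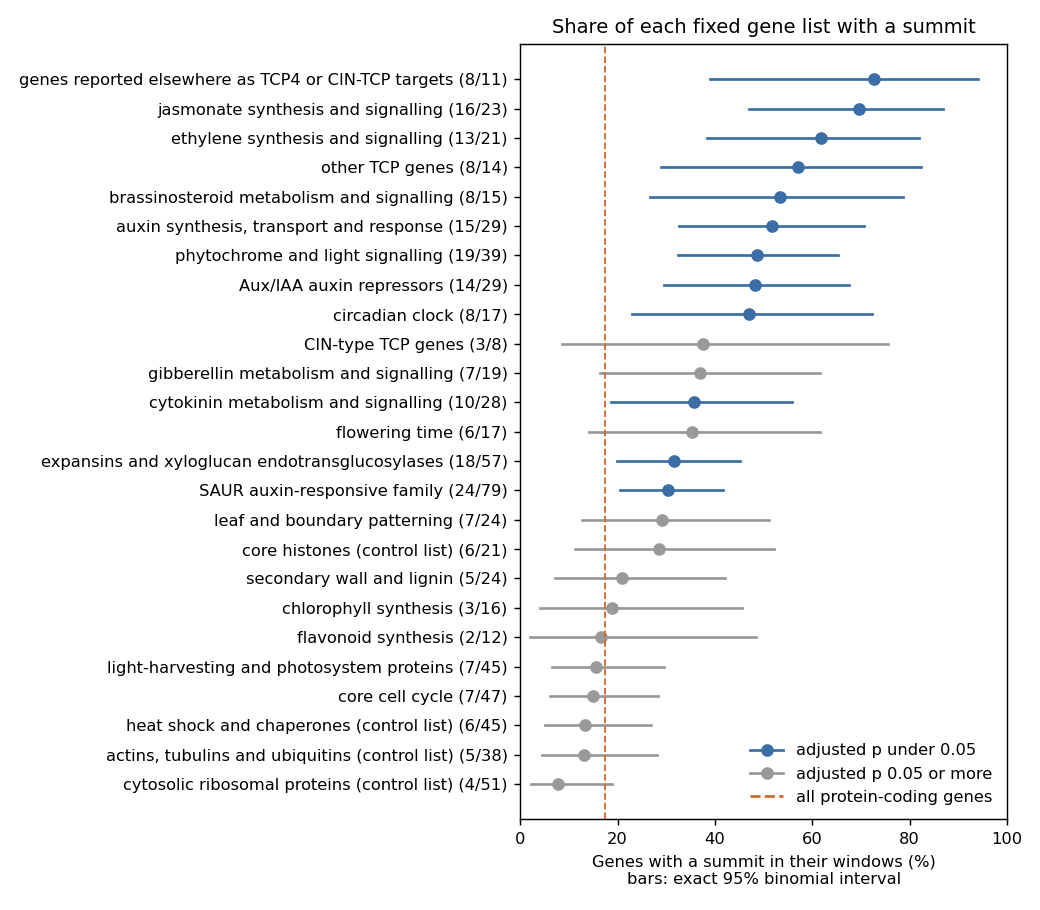
Share of each gene list with a summit in the windows at its gene ends, in percent, with exact 95% binomial intervals and the number bound out of the number of members. Lists in blue passed the adjusted test and lists in grey did not, and the dashed line is the share of all protein-coding genes, 17.4%. Jasmonate genes stand at 69.6% and ribosomal proteins at 7.84%.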

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

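The settings with nearest genes, the lowest control level, 1 summit per numbered peak and gap-matched sets were chosen only after the data were seen. The share of summits at gene ends stayed above the circular shifts in all 6 alternatives run on it. The excess was smallest at the lowest control level, 48.2% against 42.1% in the shifts, where all summits gave 62.2% against 42.2%. With the upper 50% of summits by fold, 3735 summits and 2532 bound genes were left by construction, and whole intervals of 10000 bp gave 13282 bound genes. Apart from the lowest control level, the other counts of bound genes ran from 3339 to 6788. The number of lists above other genes was 12 as reported and 8 to 15 in the alternatives run on the lists other than the lowest control level. With only those 1368 summits, 719 genes were bound and 3 lists passed. No Aux/IAA or clock gene was bound there, which gave both lists a ratio of bound shares of 0. The other lists that lost their call there had ratios of 1.96 to 5.47. With so few bound genes, counts of 0 are within chance (exact p = 1 for both lists). The SAUR ratio of bound shares, 1.75 as reported, no longer passed with nearest genes only (1.42) or at the lowest control level (2.43). It also did not pass under circular shifts, where the observed 1.75 was 1.80 times the mean ratio of the shifts. Why the call was lost in these settings was not tested. Explanations of the SAUR excess itself are weighed at the end. Among the 13 lists not called, 6 had a ratio that crossed 1 in at least 1 alternative. Alternatives for the TCP motif (other windows, a longer site, another background, strength classes, another ranking, and gene lists from motif-holding summits) were not run, since no genome sequence was used here. No paired analysis was possible because each group has 1 library. Depth limits the folds of single summits, which rest on as few as 43 fragments.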

Other observations

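The tests of symbol families, gene classes and summit numbers in this part, those on the 21 lists together, the use of summits near SAUR genes, and the shifts of SAUR counts with density were chosen only after the data were seen, as were the genes named as examples. Among 123 groups of genes that share a symbol stem and have at least 15 members, 19 were bound more often and 1 less often than other genes (Fisher's exact test, two-sided, Benjamini-Hochberg over 123 groups). Some of these stems overlap with lists of the report, such as IAA, TCP, XTH, SAUR and TIFY, and in part BBX, which shares genes with the light signalling list, and ERD, which holds AOC1 of the jasmonate list. The B-box genes (BBX) had the lowest p, with 19 of 31 bound (adjusted exact p = 7.34e-06), with BBX29 (fold 8.26), BBX30 and BBX9 at 1 shared summit (7.69) and BBX14 (7.23) beside BBX28. Genes named for an early response to dehydration (ERD) had 12 of 18 bound (adjusted exact p = 0.000308), with ERD5 (9.49) and ERD9 (6.15). Calcium-signalling kinases (CIPK) had 13 of 26 bound (adjusted exact p = 0.0044), with CIPK5 (5.47). Arabinogalactan proteins (AGP) had 14 of 31 (adjusted exact p = 0.00709), with AGP17 (8.22). WRKY transcription factors had 25 of 72 (adjusted exact p = 0.00779), with WRKY15 (8.75), and MYB genes 36 of 125 (adjusted exact p = 0.0231), with MYB62 (7.48). The group below was EMB, genes needed for embryo development, with 24 of 256 bound (9.38%, adjusted exact p = 0.00709).

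MicroRNA genes were bound in 46 of 326 cases (14.1%, exact 95% interval 10.5 to 18.4%), against 17.4% of protein-coding genes. The highest folds were at MIR405a (8.87, the summit that is also the one of IAA8), MIR167c (7.48), MIR172e (7.03), MIR396b (6.39), MIR164b (6.30), MIR393a (6.16), MIR167d (5.95) and MIR406 (5.63). MIR164A, reported elsewhere as a TCP target, had no summit within 6000 bp. Pseudogenes were bound in 67 of 3917 cases (1.71%). Megabases with under 150 protein-coding genes held 14.9 summits per 100 genes, against 28.1 in the others. The group under 150 includes incomplete last bins, those of chromosome 1 (24 summits, 133 genes) and chromosome 3 (42 summits, 148 genes). From 1000 bp outside one end to 1000 bp outside the other, 4 genes held 6 summits each. They were GA2OX6 of gibberellin breakdown, CYP707A2 of abscisic acid breakdown, AT3G57800 and the homeobox gene BEL1.

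The 21 lists other than the controls, all fixed before the data were examined, together held 564 genes, of which 201 (35.6%) were bound, a share 2.09 times that of other genes. Long intergenic flanks could raise this share, since the summed gaps to both neighbours had a median of 3458 bp in these genes and 1833 bp in others. Against 10000 gene sets matched on those gaps, the number bound was 1.99 times the mean of the sets. Their own ratios had a central 95% range of 0.83 to 1.18. This argues against gap length alone, taken over the whole genome, as the whole cause. The sets were not matched on region, and gene-poor megabases held 14.9 summits per 100 genes against 28.1 in the others. Long flanks within gene-rich regions thus stay open. Local signal in the control library is argued against for the lists together, since the ratio was 2.73 (Fisher's exact test, two-sided, p = 4.66e-08) with only the summits at the lowest control level. It is also argued against for the called lists that passed there, though on only 4 bound genes each. These were ethylene genes (4 of 21, ratio 7.31, adjusted exact p = 0.0163) and genes reported elsewhere as targets (4 of 11, ratio 13.95, adjusted exact p = 0.00333). The other 10 of the 12 called lists lost their call, with ratios of 0 for Aux/IAA and clock genes and of 1.96 to 5.47 for the rest. Against all summits, the ratio was higher there for the SAUR, other TCP, jasmonate, cytokinin and expansin lists. It was lower for auxin synthesis, transport and response, light signalling and brassinosteroid genes. For these 10 lists local signal in the control library stays open. Antibody signal of the overexpression line away from TCP4 sites and the overexpressed level of TCP4 itself stay open, as no biological explanation was tested and there is 1 library per group.

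The excess of bound SAUR genes is less secure. SAUR genes often lie in tandem, and neighbours that share a summit could inflate their count. With each summit given to its nearest gene, 17 of 79 SAUR genes (21.5%) against 15.1% of others held a summit, a ratio of 1.42 (Fisher's exact test, two-sided, p = 0.116), which lies between the bounds of 1.2 and 1.5 set in advance, so shared summits cannot be told apart from a SAUR excess with 79 genes. The density of summits around SAUR clusters, taken alone, is argued against. The number of bound SAUR genes was 1.58 times the mean of 10000 gene sets matched on the summits within 50000 bp outside their own windows, above the bound of 1.5 set in advance and the central 95% range of the sets (0.592 to 1.45, two-sided permutation p = 0.023). Those sets draw genes singly and lose the tandem layout. Circular shifts keep it, and in these the plain count of bound SAUR genes ran from 3 to 15 in 95% of shifts, against 24 observed. That count is no fair test, since shifts bound fewer genes in general (mean 3204 against 4778 observed). The ratio of bound shares allows for this. It ran from 0.329 to 1.65 in 95% of shifts against 1.75 observed, and was as large in 13 of 1000 shifts. Shifts move dense regions away from the clusters, so a last test recomputed the density and the expected count within each shift. The ratio of 1.58 then lay inside the central 95% of shifts (0.371 to 1.67, 40 of 1000 as large, two-sided permutation p = 0.0819). Tandem layout together with density thus cannot be told apart from a SAUR excess, as the shifted ratios vary widely. The tests with shifts were chosen after the earlier values were seen, and they disagree with each other on whether the excess passes.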
